A study of Homo sapiens with 4 samples.

How the data were processed

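Small RNA libraries were sequenced from PC-3 cells, an established human prostate cancer cell line, kept untreated or given apelin at 10 µg/mL for 24 h. Apelin is a secreted peptide that binds the APJ receptor. Each group had 2 libraries, named by the replicate numbers in the sample titles. The labels do not say that the libraries of a group came from separate cultures, so p-values measure only the spread between these 4 libraries, which may be technical. Per the labels' protocols, adaptors were ligated to small RNA, the cDNA was amplified by PCR, and products of 140 to 160 bp were recovered from a gel.

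The authors deposited 1 table for the series, with raw read counts and TPM values for each mature miRNA in each library and a length in nt. Per the submitters' processing notes, reads were trimmed with Trimmomatic 0.30 and DESeq2 was used. The aligner, the miRNA catalogue, the genome build and the tool behind the predicted entries are not given in the sources used here. The deposited counts are whole numbers that sum to a different total in each library. The deposited TPM values equal each count scaled to counts per 1000000 of its library's total, with no division by length. They differed from that value by at most 0.005 in 3 libraries and by at most 0.151 in apelin 2. The table lists 1096 entries, 516 with a catalogue name (prefix hsa-, left out of names here) and 580 predicted entries named NovelmiRNA with a number. Listed lengths ran from 18 to 25 nt. No column went unmatched to a sample.

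The totals were 6014838 counts in control 1, 5662879 in control 2, 5322429 in apelin 1 and 5701358 in apelin 2. A mean of 10 TPM, the minimum for testing, is worth 53.2 to 60.1 counts per library. A count of 0 allows a level of up to 3 counts, which is 0.499 to 0.564 TPM. PCR reads without molecular identifiers are not independent molecules, so this floor covers counting error only.

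The design fixed before the data were examined named limma with a mean-variance trend on log2(TPM + 1), since the deposited values were named TPM. It kept count tests as alternatives, in case whole reads could be recovered. Once the table was found to hold counts, and before any test was run, this order was reversed. edgeR's quasi-likelihood test on the counts with TMM scaling became the main test, and limma an alternative. The contrast was apelin minus control, two-sided, with Benjamini-Hochberg adjustment over the 263 tested entries (213 catalogue, 50 predicted) and a threshold of 0.05. Each SE was derived from the edgeR test, as the size of the log2 fold change over the square root of F. Confidence intervals are at 95% and use it. An exact permutation test of 2 against 2 libraries cannot give a p under 0.333. Analyses used R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

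There were 21 miRNA lists fixed before the data were examined, covering seed families, clusters, cancer, inflammation, hypoxia, vessel growth, reports on VEGF-C and apelin, and markers of other cell types. The 12 lists with at least 3 tested members were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over lists. Camera with an estimated correlation and fry were run beside it. The rule for named miRNAs was also fixed. It takes miRNAs past the threshold, or, with fewer than 20 of them, those with the smallest unadjusted p up to 20. It adds the 10 most abundant miRNAs and up to 4 of the most abundant tested members of each list. A test of the ratio of the 2 arms of a hairpin needed 20 hairpins with both arms tested and was not run, since 1 qualified.

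Besides the main test, 33 other settings were fitted, of which 18 were planned and 15 were added after seeing the data. The added ones include a run on the 207 tested catalogue miRNAs above 0 in all 4 libraries, chosen after the main test had made no call. A filter on values above 0 in every library removes entries that are at 0 in 1 group. Others were replicate numbers as a block, leaving out each library, other scalings, pseudocounts and filters, and a trend of each library against hairpin GC removed by lowess. Hairpin genes, their GRCh38 coordinates and their hosts came from GENCODE release 29. A hairpin gene was found for 512 of the 516 catalogue entries, and hairpin GC for 212 of the 213 tested. Entries named for separate copies of a mature miRNA (such as miR-92a-1-3p and miR-92a-3p) share reads, and 9 tested entries have all 4 counts in common with another, so their values are uncertain.

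The tests were checked on simulated counts, drawn independently for all 1096 entries with the real library totals. Each entry's mean was taken over only the libraries where it was above 0, which is over the real mean for entries with zeros. Every entry was given the same dispersion, the common one of the 207 miRNAs above 0 in all libraries. For edgeR 200 entries were changed in each of 20 runs. Without imposed zeros, edgeR called 89.0% of the tested entries changed 2-fold, 29.5% of those changed 1.5-fold and 0.90% of the unchanged. With zeros imposed on as many libraries of each entry as in the real table, the run on all entries called 1.98% of those changed 2-fold and 17.5% of those changed 4-fold. On simulated catalogue entries above 0 in all libraries it called 91.4% of those changed 2-fold, 29.7% of those changed 1.5-fold and 0.98% of the unchanged. Camera was run on simulated counts of the 207 miRNAs only, not on all tested entries. It called a simulated let-7 fall of 0.3 on the log2 scale in 13 of 20 runs, and called it in 0 of 20 runs with no fall. Entries were drawn independently, so these runs do not measure false calls from miRNAs that vary together.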

Results

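MicroRNAs were counted in PC-3 prostate cancer cells with and without apelin, to find those that differ under the peptide. There were 2 control and 2 apelin libraries of 5322429 to 6014838 counts each. Between 521 and 586 of the 1096 listed entries were above 0 in a library. Predicted entries held 2.87% of the counts in control 1, 2.17% in control 2, 2.62% in apelin 1 and 1.29% in apelin 2.

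No miRNA passed the edgeR test between apelin-treated and control cells, while DESeq2 called 53 entries. Of the catalogue miRNAs, let-7a-5p, a member of a family that represses RAS and HMGA2, came nearest. It stood at 55354 ± 1935 TPM (SD, n = 2) in controls and 41590 ± 3162 TPM (SD, n = 2) with apelin, a log2 fold change of -0.39 (SE 0.049, edgeR adjusted p = 0.235). miR-19a-3p, from the miR-17-92 cluster, stood at 61.9 ± 1.5 TPM (SD, n = 2) in controls and 110.3 ± 14.7 TPM (SD, n = 2) with apelin, a log2 fold change of 0.86 (SE 0.20, edgeR adjusted p = 0.627).

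The edgeR quasi-likelihood test called 0 of 263 entries. At an unadjusted p under 0.05 there were 15 entries, 9 catalogue and 6 predicted. The 20 entries with the smallest p held 12 catalogue miRNAs, none of them past the threshold in edgeR. Those with a negative log2 fold change were let-7a-5p, let-7d-5p (-0.37, SE 0.094), miR-181b-5p (-0.36, SE 0.094), miR-10a-5p (-0.25, SE 0.071) and miR-424-3p (-0.49, SE 0.15). Those with a positive one were miR-19a-3p, miR-20a-5p (0.44, SE 0.13), miR-17-5p (0.38, SE 0.12), miR-19b-1-3p (0.61, SE 0.20), miR-3613-5p (0.80, SE 0.22), miR-29a-3p (0.31, SE 0.092) and miR-22-3p (0.44, SE 0.14). Without apelin 2 miR-20a-5p was 0.28, miR-17-5p 0.23, miR-19b-1-3p 0.34, miR-29a-3p 0.15 and miR-22-3p 0.24. Limma on log2(TPM + 1), the test first planned, called 4 entries, all predicted and all at 0 in some library. DESeq2 called 53, of which 30 were at 0 in some library. The other 23 included 11 of the 12 catalogue miRNAs above, all but miR-29a-3p, with let-7a-5p at an adjusted p = 2.67e-09 and miR-19a-3p at 0.000228. Without control 1 edgeR called 11 entries and without control 2 it called 19, and every one of these was at 0 in some library. A run on the 207 catalogue miRNAs above 0 in all 4 libraries was chosen after seeing the data. In it edgeR called 0 (17 at an unadjusted p under 0.05), and DESeq2 and limma called 0 each. With replicate numbers as a block edgeR called 30 of the 207, but the labels do not pair libraries by number. The apelin and control libraries did not overlap for 83 of these 207 miRNAs (40.1%), where chance gives 33.3%.

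By mean TPM over the libraries the most abundant miRNA was miR-21-5p, though miR-100-5p stood higher in control 1 (95571 TPM). miR-21-5p had 91403 and 103045 TPM in controls 1 and 2, and 113810 and 168194 TPM in apelin 1 and 2. Its log2 fold change was 0.57 (SE 0.27, edgeR adjusted p = 0.627), so it did not pass, and it was 0.15 without apelin 2. miR-100-5p stood at 93625 ± 2752 TPM (SD, n = 2) in controls and 84703 ± 1844 TPM (SD, n = 2) with apelin. The paired neighbours miR-221-3p and miR-222-3p, which repress the cell cycle inhibitor p27, had log2 fold changes of 0.041 (SE 0.078) and 0.058 (SE 0.050), or -0.082 and 0.024 without apelin 2. The rest of the 10 most abundant were let-7a-5p, miR-125b-5p, miR-23a-3p, miR-30d-5p, miR-125a-5p and miR-92a-1-3p, and their adjusted p ran from 0.235 to 0.876 in edgeR.

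The entries with the smallest p of all were predicted ones listed at 0 in a whole group. NovelmiRNA-400 had 10381 and 11116 counts in the controls and 0 in both apelin libraries (edgeR adjusted p = 0.0687). NovelmiRNA-295, NovelmiRNA-456 and NovelmiRNA-526 had identical counts, 0 in both controls, 5897 in apelin 1 and 4558 in apelin 2 (edgeR adjusted p = 0.0687). Of the tested entries, 47 were at 0 in some library and at 100 counts or more in another, 41 predicted and 6 catalogue. In 39 of the 47 the libraries of a group parted, one at 0 and the other at 100 counts or more, and 7 of the 47 split by group. Catalogue examples were miR-1260a with 31145 counts in control 2 and 0 in the other libraries, and miR-4521 with 3186 in control 2 and 0 in the others. Of the 20 entries with the smallest p, 8 were predicted. NovelmiRNA-558 (859 and 374 counts in the controls) and NovelmiRNA-517 (546 and 11948) were also at 0 in both apelin libraries. NovelmiRNA-553 had the same control counts as NovelmiRNA-558 but 319 counts in apelin 2. The counts of NovelmiRNA-517 were also those of NovelmiRNA-9 in control 1 (546) and of NovelmiRNA-325 in control 2 (11948). NovelmiRNA-26 and NovelmiRNA-450 were above 0 in all libraries, with log2 fold changes of -1.25 (SE 0.22, edgeR adjusted p = 0.460) and -1.40 (SE 0.44, edgeR adjusted p = 0.627), and DESeq2 called both (adjusted p = 4.70e-11 and 0.00657). NovelmiRNA-450 was -0.85 without control 1. Counts and no folds are given for the entries at 0, since their libraries of a group parted so often.

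**Figure D1:**
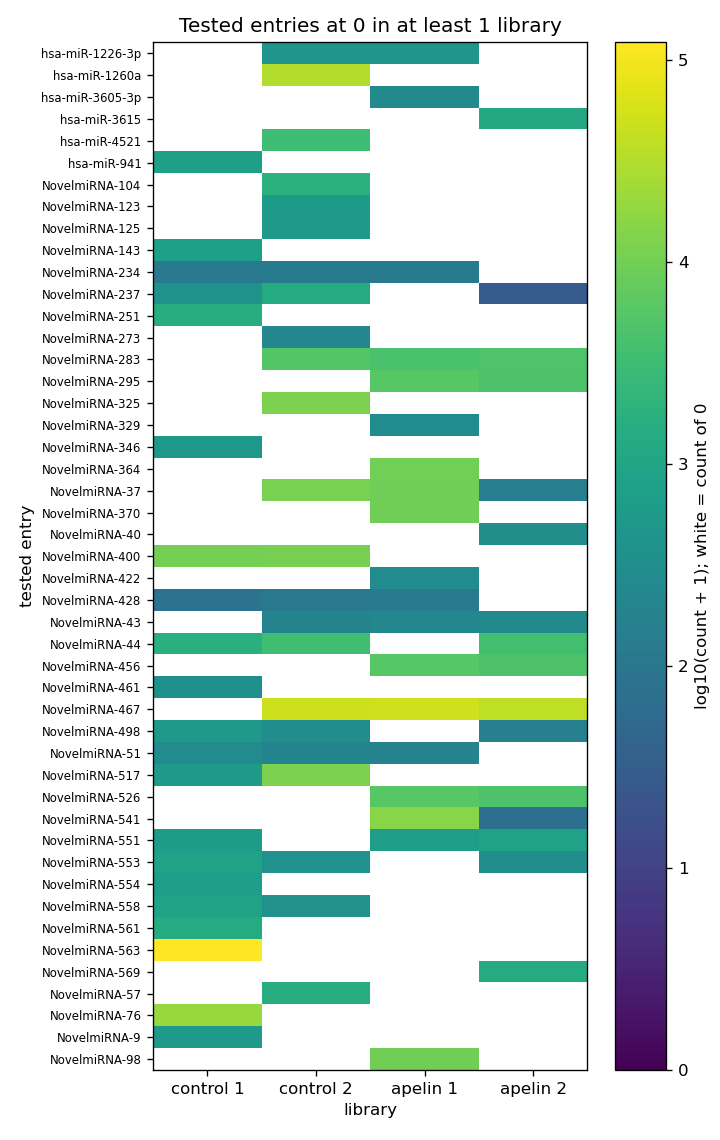
Counts per library (columns) of the 47 tested entries (rows) that were at 0 in some library and at 100 counts or more in another, as log10(count + 1), with a count of 0 in white. In 39 of the 47 rows the libraries of a group part, and 7 rows split by group.

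Among the fixed lists, the let-7 family had the lowest median log2 fold change and the miR-17-92 clusters the highest, and neither passed the test. Of the 9 let-7 members, 8 had lower fitted values with apelin, though under quantile normalization let-7b-5p (0.053) and let-7g-5p (0.22) turned higher and let-7i-5p (-0.051) lower. With a library left out let-7b-5p turned to 0.035 (without control 1), let-7g-5p to 0.12 (without apelin 1) and let-7i-5p to -0.19 (without apelin 2). In both apelin libraries 4 members (let-7a-5p, let-7c-5p, let-7d-5p and let-7e-5p) lay below both controls. The list's median log2 fold change was -0.23 (camera adjusted p = 0.141). With an estimated correlation camera gave an adjusted p = 0.870 (0.119 unadjusted, against 0.0118 with the preset). The correlation estimated for let-7 was -0.033, so correlation among its members does not account for the higher p. In edgeR 0 of 9 members were called over all entries, and 1 (let-7a-5p, adjusted p = 0.0401) adjusted over the list alone. That call ended in the run on 207 catalogue miRNAs (smallest adjusted p = 0.0730), where let-7a-5p had a log2 fold change of -0.41 (SE 0.11). With hairpin GC removed there, 1 member was called over the list alone (adjusted p = 0.0410). DESeq2 over all entries called members such as let-7a-5p (adjusted p = 2.67e-09) and let-7d-5p (1.18e-06), but 0 in the run on 207. Of 9 tested members of the miR-17-92 cluster and its paralog clusters, a MYC-driven group tied to proliferation, 6 lay above both controls in both apelin libraries: miR-17-5p, miR-18a-5p, miR-19a-3p, miR-20a-5p, miR-106a-5p and miR-106b-5p. miR-106a-5p did so only narrowly, with 22.63 TPM in apelin 2 against 22.43 TPM in control 2. The other 3, miR-92a-3p (-0.10, SE 0.20), miR-93-5p (-0.21, SE 0.11) and miR-25-3p (-0.057, SE 0.091), had negative log2 fold changes, though miR-92a-3p was 0.011 without apelin 2 and 0.013 without control 1. The median was 0.40 (camera adjusted p = 0.162, and adjusted p = 0.870 with an estimated correlation, which was 0.12). In edgeR 0 of 9 members were called over all entries and 0 adjusted over the list alone. DESeq2 over all entries called members such as miR-19a-3p (adjusted p = 0.000228), miR-20a-5p (0.00151) and miR-17-5p (0.00467), but 0 in the run on 207 catalogue miRNAs. miR-19b, listed only under copy names, was left out of this list. Adding miR-19b-1-3p in the run on 207, chosen after seeing the data, gave 10 tested members. Of these, 7 lay above both controls in both apelin libraries (camera adjusted p = 0.00745, and adjusted p = 0.865 with an estimated correlation, which was 0.19).

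**Figure D2:**
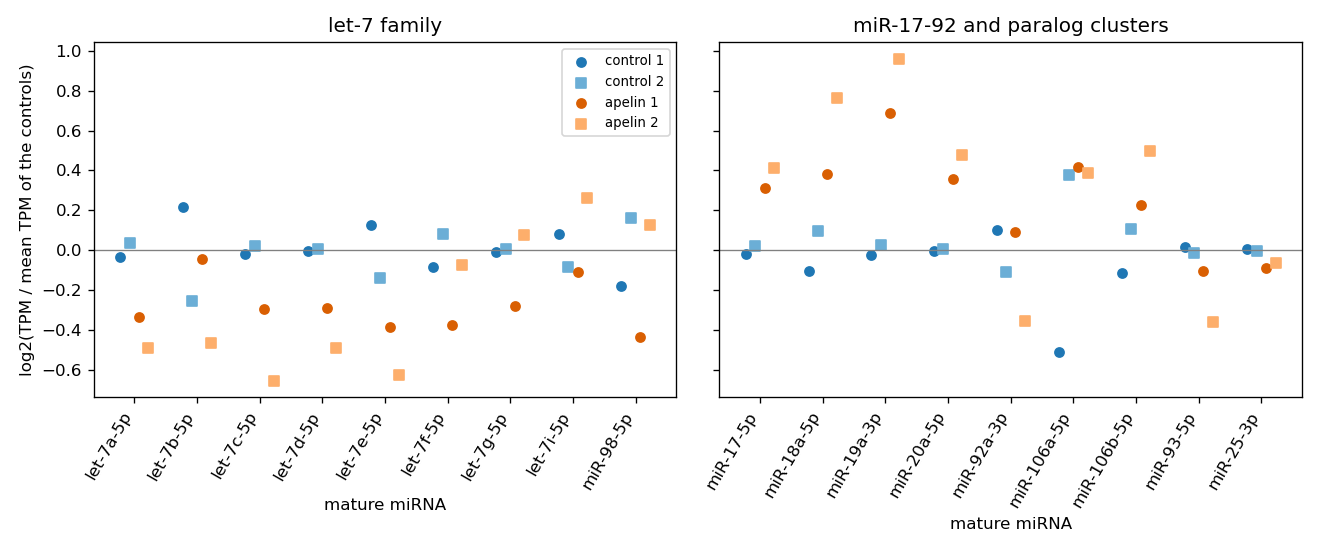
TPM of each tested member (x axis) of the let-7 family and of the miR-17-92 and paralog clusters in each library, as log2 of its ratio to the mean of the controls (y axis). Of 9 let-7 members 4 lie below both controls in both apelin libraries, and of 9 miR-17-92 members 6 lie above both, miR-106a-5p only narrowly.

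Both lists were called only under settings other than the main one. In the run on 207 catalogue miRNAs, chosen after seeing the data, the let-7 median was -0.24 (camera adjusted p = 0.00452). With an estimated correlation, which was -0.10 for let-7, camera's adjusted p was 0.771 (0.0643 unadjusted). The miR-17-92 median in that run was 0.38 (adjusted p = 0.0423, and adjusted p = 0.820 with an estimated correlation, which was 0.12). Without apelin 1 the let-7 call in that run ended (median -0.41, adjusted p = 0.212). The miR-17-92 call ended without any of the 4 libraries (median 0.30 and adjusted p = 0.178 without control 1, 0.41 and 0.129 without control 2, 0.47 and 0.160 without apelin 1, and 0.27 and 0.101 without apelin 2). Over the 30 alternatives the let-7 median stayed between -0.42 and -0.18 with 14 calls (adjusted p from 3.42e-06 to 0.750), and the miR-17-92 median between 0.23 and 0.47 with 3 calls (adjusted p from 0.00745 to 0.790).

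The let-7a-1, let-7f-1 and let-7d hairpins lie together on chromosome 9 from 94175957 to 94178920 (GRCh38, plus strand), in introns of the lincRNA AL158152.2. let-7a-5p also comes from MIRLET7A2 on chromosome 11 (122146522 to 122146593, in an intron of MIR100HG) and MIRLET7A3 on chromosome 22 (46112749 to 46112822, in an exon of MIRLET7BHG), so its count does not say which hairpin it came from. let-7 members differ by few bases, and the authors' counting of reads shared between them is not given in the sources used here. The miR-17-92 hairpins lie on chromosome 13 from 91350605 to 91351391, in the host transcript MIR17HG. MIR21 lies on chromosome 17 from 59841266 to 59841337, in an exon of VMP1.

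The other 10 tested lists gave no call with camera, and none had a member called by edgeR. DESeq2 over all entries called some members, such as miR-30d-5p (adjusted p = 0.0112), miR-200c-3p (0.0376) and miR-181b-5p of the hypoxia list (3.05e-05). miR-29 and miR-30, which repress collagens and EMT genes, had a median of 0.22 (camera adjusted p = 0.408), which was 0.0064 without apelin 2 and 0.35 without apelin 1. 5 of the 7 members had positive values, among them miR-29a-3p at 23742 ± 1311 TPM (SD, n = 2) in controls and 28925 ± 1461 TPM (SD, n = 2) with apelin. The NF-kB and inflammation list had a median of 0.26 (adjusted p = 0.593), with miR-146a-5p at 0.29 (SE 0.15), or 0.13 without apelin 1. miRNAs reported to act on VEGF-C, the lymphatic growth factor in the study's title, had 3 tested members and a median of 0.061 (adjusted p = 0.691). These were miR-101-3p (0.60, SE 0.28, and 0.21 without apelin 2), miR-186-5p (0.061, SE 0.095) and miR-27b-3p (0.033, SE 0.19). Without apelin 2 miR-186-5p turned to -0.029 and miR-27b-3p to -0.22. Entries named for separate copies were left out of this list. Adding them, in the run on catalogue miRNAs above 0 in all libraries, chosen after seeing the data, gave 4 tested members. Of these, 3 were higher and 1 was lower, and the lower one lay below both controls in both apelin libraries. The median there was 0.035 (camera adjusted p = 0.813). The miR-15/16 family had a median of 0.14, the miR-23-27-24 clusters 0.033, the prostate oncomiRs 0.041 and the angiogenesis list 0.041 (adjusted p = 0.691, 0.691, 0.816 and 0.691). The hypoxia and HIF list had a median of 0.012 (adjusted p = 0.993). The miR-200 family, which represses ZEB1 and ZEB2, had a median of 0.024 with a mean of -0.026, and the prostate tumour suppressors a median of 0.00089 with a mean of -0.049. Camera put both of these lower (adjusted p = 0.816 and 0.691), against the sign of their medians. Without apelin 2 the medians of 8 of these 10 lists were negative: NF-kB -0.070, VEGF-C-linked -0.029, miR-15/16 -0.062, miR-23-27-24 -0.061, oncomiRs -0.082, hypoxia -0.28, miR-200 -0.20 and tumour suppressors -0.22. In that fit the median over all 264 tested entries was -0.059, against -0.018 in the main one. Several of these list medians therefore lay near that of the entries as a whole. Adjusted over the list alone, 0 members of each of these lists were called by edgeR.

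**Figure D3:**
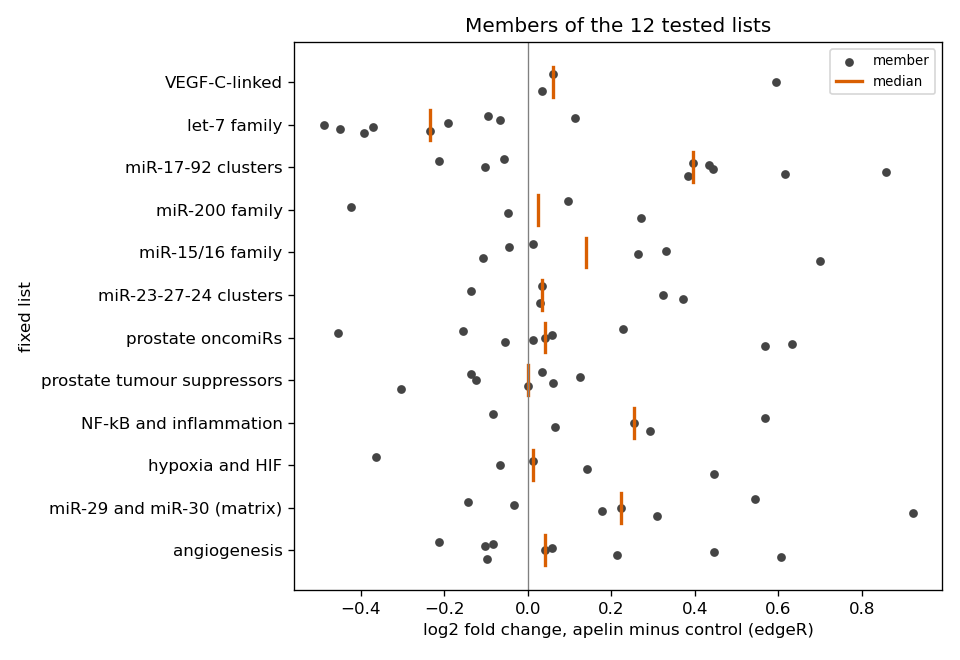
edgeR log2 fold change (x axis, apelin minus control) of each tested member (points) of the 12 tested lists (rows), with each list's median as a vertical line. Medians run from -0.23 for let-7 to 0.40 for miR-17-92, and no list passed the test.

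Lists with fewer than 3 tested members were described only. Of the apelin-linked miRNAs, miR-503-5p had a log2 fold change of 0.013 (SE 0.18) and miR-106a-5p of 0.44 (SE 0.39), which was 0.057 without control 1 and 0.88 without control 2. miR-34a-5p, induced by p53, had 0.23 (SE 0.21). Without apelin 2 miR-503-5p was -0.11 and miR-34a-5p -0.047. Markers of other cell types were low or gave no call: the red cell miRNA miR-486-5p stood at 36.4 ± 0.9 TPM (SD, n = 2) in controls and 31.0 ± 3.9 TPM (SD, n = 2) with apelin, and the liver miRNA miR-194-5p had 0.38 (SE 0.16) and miR-192-5p 0.24 (SE 0.17). miR-10b-5p, from the stromal list, had -0.098 (SE 0.11), and miR-9-5p, from the neuronal list, had 0.26 (SE 0.23), or -0.072 without apelin 2. The muscle, 14q32 and C19MC lists had 0 tested members.

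The 10 most abundant miRNAs held 51.96% ± 0.64 (SD, n = 2) of the counts in controls and 52.4% ± 0.99 (SD, n = 2) with apelin. The difference of 0.46 percentage points was within the spread of the replicates (exact permutation test, two-sided, p = 0.667, where 0.333 is the smallest possible). It turned to -0.24 without apelin 2.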

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

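Settings on the 207 catalogue miRNAs above 0 in all libraries, on catalogue names alone, with copies collapsed, with copy names in lists, with hairpin GC removed and with edgeR's robust option were chosen only after seeing the data; the rest were planned. The main count of called entries was 0 in edgeR. It was 0 too at a mean of 1 TPM, with library totals or DESeq2 size factors and in all added settings except the blocked one. Limma on log2(TPM + 1) gave 4, with 0.1 or 10 as pseudocount 5 and 4, centred 5, with quantile normalization 4, without a trend 5 and with a robust trend 5. A minimum of 100 TPM gave 4, no filter 52 and DESeq2 53. Leaving out a library gave 0 to 19. Called entries were at 0 in some library in all of these except 23 with DESeq2 and 1 with no filter. With a replicate block edgeR called 0 of 263 (50 at an unadjusted p under 0.05) and 30 of the 207. The labels do not pair libraries by number, and same-numbered deviations correlated at 0.318 over miRNAs. The main count of called lists was 0. It was 1 (let-7) with limma at a pseudocount of 0.1 or 10 or centred, and with catalogue names alone. On the 207 it was 2, also with library totals or copy names, and 1 with GC removed, a replicate block or limma. Leaving out a library gave 0 to 1. Estimated correlation and fry gave 0. The planned arm-ratio test and its alternatives were not run, as 1 hairpin qualified. The group difference in the top 10 share, 0.46 percentage points, was 1.69 for the top 5, 1.65 for the top 20 and -0.24 to 1.17 with a library left out.

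Of 58 log2 fold changes, 35 kept their direction in all settings and 23 reversed in at least 1, 13 of them with all libraries kept. Of 12 list medians, 4 kept it and 8 reversed, 4 of them with all libraries kept. The cause was not tested, except that leaving out a library leaves fewer samples. None of the reversed values was past the threshold in edgeR on all entries. Under quantile normalization miR-503-5p was -0.039, let-7i-5p -0.051, let-7g-5p 0.22, let-7b-5p 0.053, miR-429 -0.038, miR-107 -0.032 and the medians of miR-200 -0.078, tumour suppressors -0.035 and hypoxia -0.032. Limma at any pseudocount, with no trend, with a robust trend or on the 207 gave -0.020 for miR-31-5p and the tumour suppressor median, -0.030 for miR-26b-5p and the hypoxia median, and -0.0048 for the miR-200 median (-0.0054 at a pseudocount of 10). Library totals gave -0.013 for miR-503-5p, -0.021 for miR-31-5p and tumour suppressors, -0.020 for miR-26b-5p and hypoxia and -0.0024 for miR-200. Library totals on the 207 gave -0.0060 for miR-23a-3p and the miR-23-27-24 median, -0.0090 for miR-27b-3p, -0.026 for miR-503-5p, -0.033 for miR-31-5p and tumour suppressors, -0.034 for miR-26b-5p and hypoxia and -0.016 for miR-200. miR-31-5p was -0.0049 with DESeq2 and with its size factors, as was the tumour suppressor median with the latter. Both were -0.011 with catalogue names alone, on the 207 and with the block there, as was that median with copy names. There DESeq2 gave miR-31-5p -0.0079 and miR-26b-5p -0.00014. miR-503-5p was -0.00023 with catalogue names alone and -0.00018 on the 207. The block gave -0.0098 for miR-26b-5p and hypoxia, and -0.022 for both on the 207, where copy names gave hypoxia -0.00095. Removing GC gave miR-186-5p -0.15, miR-25-3p 0.060 and miR-200b-3p 0.053.

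With each library left out in turn, over all entries and over the 207, log2 fold changes ran from -0.082 to 0.10 for miR-221-3p, -0.061 to 0.074 for miR-23a-3p, -0.32 to 0.043 for miR-92a-1-3p, -0.31 to 0.049 for miR-92a-3p and -0.22 to 0.20 for miR-27b-3p. They ran from -0.029 to 0.10 for miR-186-5p, -0.18 to 0.19 for miR-503-5p, -0.19 to 0.32 for let-7i-5p, -0.36 to 0.13 for let-7g-5p and -0.49 to 0.049 for let-7b-5p. For miR-200a-3p the range was -0.042 to 0.49, for miR-429 -0.26 to 0.33, for miR-16-5p -0.015 to 0.45, for miR-34a-5p -0.047 to 0.43 and for miR-31-5p -0.094 to 0.033. For miR-9-5p it was -0.072 to 0.48, for miR-146b-5p -0.10 to 0.22, for miR-26a-5p -0.28 to 0.084, for miR-26b-5p -0.36 to 0.26, for miR-107 -0.027 to 0.24 and for miR-30a-5p -0.093 to 0.36. List medians ran from -0.029 to 0.20 for VEGF-C-linked, -0.20 to 0.16 for miR-200, -0.062 to 0.24 for miR-15/16, -0.061 to 0.20 for miR-23-27-24 and -0.082 to 0.067 for oncomiRs. They ran from -0.22 to 0.033 for tumour suppressors, -0.070 to 0.27 for NF-kB and -0.28 to 0.17 for hypoxia. Of the 58, 25 others kept their direction but moved by over 1.5 times in some of these fits. Those with a value in the text ran from 0.15 to 0.85 for miR-21-5p, 0.21 to 0.86 for miR-101-3p, 0.057 to 0.89 for miR-106a-5p, 0.28 to 0.54 for miR-20a-5p, 0.23 to 0.47 for miR-17-5p, 0.34 to 0.80 for miR-19b-1-3p and 0.15 to 0.40 for miR-29a-3p. They ran from 0.24 to 0.57 for miR-22-3p, 0.019 to 0.067 for miR-222-3p, -0.17 to -0.0075 for miR-25-3p, 0.13 to 0.41 for miR-146a-5p, 0.24 to 0.49 for miR-194-5p, 0.085 to 0.33 for miR-192-5p and -0.19 to -0.030 for miR-10b-5p. The 4 medians that kept their direction moved as far, from 0.0064 to 0.36 for miR-29 and miR-30, 0.0034 to 0.067 for angiogenesis, -0.42 to -0.26 for let-7 and 0.23 to 0.47 for miR-17-92. The lone library left in a group was assumed to vary like the other group. The minimum for testing, a mean over the libraries, is worth 53.2 to 60.1 counts per library; entries with a lower mean were not tested, while tested entries can lie below it in single libraries.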

Other observations

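All tests in this part were chosen only after the patterns they address were seen; for GC and length the bounds were set before their values were computed.

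Hairpins within 10 kb of each other on a strand were grouped after the data were examined, and these groups were not tested. Of the 11 groups, 1 had all entries higher, 1 had all lower and 9 had entries both ways. In the run on 207 catalogue miRNAs, the 3 miRNAs of the let-7a-1, let-7f-1 and let-7d hairpins on chromosome 9 were all lower with apelin, with a median log2 fold change of -0.38. The 4 entries of the MIR23A, MIR27A and MIR24-2 hairpins on chromosome 19 (13836287 to 13836659) were higher, with a median of 0.31, but miR-24-2-3p and miR-24-3p had identical counts, and miR-23a-3p (0.017, SE 0.12) turned to -0.038 without control 1, -0.023 without apelin 2 and -0.0060 with library totals. For the paralog cluster MIR23B, MIR27B and MIR24-1 on chromosome 9, 3 of 4 entries were higher, with a median of 0.17, and the miR-24 entries of both clusters share reads. The MIR17HG cluster had 5 of 7 entries higher, with a median of 0.43, and its paralog MIR106B, MIR25 and MIR93 within MCM7 had 1 of 3 higher, with a median of -0.068. The paralog MIR106A, MIR19B2 and MIR92A2 on chromosome X had 2 of 4 higher (0.15). The others were MIR200A, MIR200B and MIR429 (2 of 3 higher, median 0.084), MIR182, MIR183 and MIR96 (2 of 3, 0.0013), MIR362 to MIR660 (4 of 7, 0.036), MIR424 to MIR542 (3 of 5, 0.12) and MIR105 with MIR767 (1 of 2, -0.13). None of the single miRNAs in these groups passed the edgeR test in this run.

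Of the tested entries, 47 were at 0 in some library and at 100 counts or more in another. Apelin treatment does not account for them as a set, since in 83.0% the libraries of a group parted. The 7 that split by group stay open, except NovelmiRNA-558, whose 0 in apelin 2 is weighed below. These 7 are not separate differences, since NovelmiRNA-295, NovelmiRNA-456 and NovelmiRNA-526 have identical counts. For predicted entries, the values argue against sampling at this depth that acts alike on predicted and catalogue entries. Among distinct entries with 100 to 1000 counts in one library, 28.6% to 53.3% of the predicted ones were at 0 in the other library of the group. The share for catalogue ones was 1.47% to 2.82% (Fisher's exact test across entries, two-sided, largest of 4 p = 0.00587). Predicted entries that share counts in some libraries but not in all entered as separate ones, so this p is not exact. Loss of molecules before PCR that differs between entries stays open. For the 6 catalogue entries among the 47, counting of reads is excluded, since the library at 0 had an expected count of at least 277 from the other library of its group, where a 0 allows 3 counts; loss of molecules before PCR stays open. For some predicted entries, reads missing from one entry were listed under another. NovelmiRNA-44 and NovelmiRNA-270 both had 1682 counts in control 1, 3398 in control 2 and 3526 in apelin 2, but 0 and 2134 in apelin 1. NovelmiRNA-558 and NovelmiRNA-553 both had 859 and 374 in the controls and 0 in apelin 1, but 0 and 319 in apelin 2. These values argue against absent RNA as the cause of those zeros. How reads were assigned to entries is not given in the sources used here, and its part in the other zeros stays open.

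The second pattern is let-7 members lower and miR-17-92 members higher with apelin, in the run on 207 miRNAs. For let-7, removing the trend against hairpin GC left the median at -0.32 against -0.24 (camera adjusted p = 0.00120). With an estimated correlation, which was 0.014, camera's adjusted p was 0.717. The summed let-7 level differed by -18696 TPM against at most 2134 within a group. Scaling without miR-21-5p left a median of -0.17 of -0.24. So none of the hairpin GC trend, reads moved between members or miR-21-5p was the whole cause. Hairpin GC is not the GC of the mature sequences, which was not tested, so GC-dependent recovery of these stays open. For miR-17-92 the same GC correction ended the call with a smaller median (0.29, SD over members 0.31, adjusted p = 0.0534, from 0.38, SD 0.36, and 0.0423) although 74.7% of the median was left, so a part from GC cannot be told apart from other causes. Apelin treatment stays open, with no test of it beyond those of the lists, and in the edgeR fit over all entries with all libraries these gave no call.

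The third pattern is that libraries of a group differed, by an SD over miRNAs of 0.31 on the log2 scale for the ratio of the controls and 0.40 for that of the apelin libraries. For the difference of the group means it was 0.31, where 0.25 is expected with no group difference if libraries vary independently. Across 206 miRNAs, which are not independent replicates, the log2 ratio of libraries 1 and 2 had a Spearman correlation with hairpin GC of 0.23 in controls and 0.48 with apelin, and with listed length of 0.10 in controls and -0.12 with apelin. Neither GC (smaller value 0.226) nor length (0.102) passed or fell under its bound in both groups, so their part cannot be told apart from other differences between libraries. The difference of the group means, apelin minus control, had a Spearman correlation of -0.27 with hairpin GC and 0.15 with listed length. So the log2 fold changes can hold a part tied to GC. No biological explanation was tested here.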
